A study of Homo sapiens with 8 samples.

How the data were processed

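RNA was taken from stretched A549 cells sorted as β-galactosidase positive (4 libraries) or negative (4 libraries). Total RNA was extracted with Trizol and libraries were made with a targeted amplicon kit for human transcripts on the Ion Torrent platform, per the labels' protocols. Such a kit amplifies a short stretch of each gene, so a count does not scale with transcript length as in whole-transcript sequencing, and a gene with no amplicon is not measured. Per the submitters' processing notes, fastp 0.20.1 and Salmon 1.9 were used with the human build GRCh38. The transcript annotation, how transcripts were summed to genes and how rows were filtered are not given in the sources used here. The deposited values are estimated counts per gene, already whole numbers, so rounding to whole numbers altered nothing, and they were not scaled to a common depth. Each of the 13841 rows was above 0 in at least 5 of the 8 libraries. In all, 58 symbols stood on 148 rows, 29 of which were identical to another row of the same symbol, and such rows were kept apart and named by symbol and row. Of 13751 distinct symbols, 13386 were matched to the GENCODE annotation of GRCh38, 429 through a RefSeq synonym, and coordinates are from that annotation.

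Each library was placed in its group by its label, and since each library number was used once, the labels give no pairing and none was fitted. Whether positive and negative cells were sorted from the same cultures is not given in the sources used here. Depth ranged from 5634961 to 7990839 counts. Intervals cover the spread between libraries, and amplicon reads carry no molecular identifiers. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 7.98.

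Genes were kept with filterByExpr (a minimum count of 10 and a total of 15), which left 11351 rows and removed 2490. They were tested with edgeR 4.0.16 (TMM scaling and the quasi-likelihood test with robust estimation, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM-scaled. Of 30 gene lists fixed beforehand, 28 had 5 or more tested members and were tested with camera (limma 3.58.1) on log2-CPM values with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. A list score was the mean log2-CPM of the tested members of a list, compared by an exact two-sided permutation test over the 70 assignments of 4 against 4, which cannot go below 0.0286. After adjustment over 28 lists no score can therefore pass 0.05 unless many lists reach that smallest p.

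The tests, lists, alternatives and the rule for named genes were chosen before the data were examined. The rule took the 10 genes of largest change in each direction among those past the threshold, with a mean of at least 5 CPM in the higher group and no overlap between groups, and, since fewer than 5 genes passed, the 10 of smallest p in each direction. It added fixed markers and, of each list, the members of smallest p, 4 for each of 8 lists on the cell cycle, p53, senescence, secretion, fibroblast activation and lysosomes and 3 for the others. This gave 125 genes, of which a few are not reported here.

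Alternatives were other scalings, low-count filters, thresholds and tools (DESeq2 1.42.0 and limma voom with library weights), robust estimation off, thinning of all libraries to the smallest total, 1 surrogate variable (sva 3.50.0), lists without shared members and each library left out in turn. Chosen after seeing the data were the removal of both positive 1 and negative 2, the summing of rows of 1 symbol, and the removal of a smooth curve over transcript length and GC content, for which 98.2% of tested genes had a value. Length and GC content were those of the longest annotated transcript, not of the amplicon. A list of transcripts often retained in the nucleus was also written after the components of the libraries had been seen.

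The methods were tested on simulated counts with the means, depths and dispersions of these libraries, in 5 runs with 200 changed genes each over 11351 genes. Of the calls 6.32% were false, a list of 40 genes shifted by 0.4 on the log2 scale was called in 5 of 5 runs, and 0 of 135 lists of unchanged genes were called. The simulated genes vary independently of each other, so the runs do not test how camera behaves when genes vary together.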

Results

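Gene expression was measured in A549 cells, an established line from a human lung adenocarcinoma that is widely used to stand for alveolar epithelium. The cells had been stretched cyclically (15% elongation, 15 cycles per min, 24 h) and sorted after another 6 days of culture by their β-galactosidase activity, a lysosomal activity that is raised in senescent cells. The 8 libraries comprised 4 of positive cells (numbers 1, 3, 4 and 5) and 4 of negative cells (numbers 2, 6, 7 and 8). Total counts were 5634961, 7418432, 7405191 and 7241677 in positive 1, 3, 4 and 5, and 7990839, 6121383, 6764113 and 6615081 in negative 2, 6, 7 and 8. The comparison asks which transcripts set stained cells apart from unstained cells after stretch, in a series about stretch-induced senescence and paracrine activation of fibroblasts. Unstretched cells were not analysed here. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

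Genes for subunits of the respiratory chain and ATP synthase, targets of the antioxidant factor NRF2, and genes of the cell cycle, histones and ribosomes were lower as groups in the positive cells, and targets of the inflammatory factor NF-kappaB were higher, by a test that presets the correlation between genes. None of these groups passed when that correlation was estimated from the libraries. Leaving out single libraries ended 5 of the 7 calls. The histone call was lost without negative 2 (adjusted p 0.394), the ribosome call without negative 2 (0.602) or positive 1 (0.114), the replication call without negative 2 (0.922), positive 3 (0.236) or positive 4 (0.0669) and the mitosis call likewise (0.700, 0.454 and 0.0560). The NF-kappaB call was lost without positive 1 (0.430), negative 6 (0.214), positive 3 (0.0524) or negative 7 (0.0511). The oxidative phosphorylation and NRF2 calls held with each library left out (adjusted p at most 7.73e-05 and 0.0482). They also held without both positive 1 and negative 2, which stood apart from the rest (0.00105 and 0.0493). Most other groupings of 4 against 4 libraries that part positive 1 and negative 2 also called the oxidative phosphorylation list, at camera adjusted p down to 7.77e-07. For that list, holding thus does not set the real grouping apart. Whether other groupings also call the NRF2 list was not tested. Of all 35 groupings, 23 called at least 7 lists. The NRF2 call was lost when genes needed at least 50 counts in each library of a group. In edgeR's test 0 genes passed, with 1631 at an unadjusted p under 0.05, limma voom called 0 and DESeq2's Wald test called 45, LIMK1 among them. The genes with the smallest p included LIMK1, a kinase that controls actin filaments, at 112 ± 8.35 CPM in positive and 68.0 ± 7.09 in negative cells (SD, n = 4 each), and RPA1, a subunit of the protein that coats single-stranded DNA, at 71.5 ± 2.29 and 117 ± 26.97 CPM. The 95% intervals of markers of senescence chosen as single genes, such as CDKN1A and LMNB1, spanned 0. Those of PLAUR and BMI1, named from a fixed list for their small p, did not. Of all tested genes 14.4% had an unadjusted p under 0.05.

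Of 11351 genes tested, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, the smallest adjusted p being 0.309. At an unadjusted p under 0.05 there were 1631 genes, 854 higher and 777 lower in the positive cells, where 568 would follow from uniform p-values. DESeq2's Wald test called 45 genes, 37 higher and 8 lower, and limma voom with library weights called 0. The 4 values of one group lay wholly above those of the other for 1037 genes, or 9.14%, where chance gives 2.86%. In simulated counts of this size the test recovered 5.07% of genes changed 1.5-fold, 35.2% of those changed 2-fold and 93.6% of those changed 4-fold. No simulated library stood apart and simulated genes shared no variation, so these shares may be too high for the real libraries. Genes with estimates beyond 4-fold, such as BSCL2 (log2 fold change -2.77) and PRR3_row3 (-2.44), did not pass. In the real data the median half-width of the 95% interval of a log2 fold change was 0.54.

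Among the genes of smallest p that were higher in the positive cells, none past the threshold (edgeR adjusted p 0.309 for each), the log2 fold change was 1.84 ± 0.34 (SE) for CRNKL1, a splicing factor, and 0.72 ± 0.15 for LIMK1. It was 1.65 for JAG2, a Notch ligand, 1.37 for AGER, a receptor typical of alveolar type 1 cells, 1.12 for TP53I13 and 1.12 for ZNF276. FBXL8 (1.36), MYL5 (1.45), ACCS (1.41) and the processed pseudogene TCEA1P2 (1.54) completed the higher genes. DESeq2's Wald test called all 10 of them, at adjusted p from 0.0179 (CRNKL1 and LIMK1 among them) to 0.0495 (AGER). CRNKL1 lies on chromosome 20 at 20034368 to 20056046 and LIMK1 on chromosome 7 at 74082933 to 74122525, in GRCh38 with GENCODE annotation. Both are protein-coding.

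Among those lower in the positive cells, again at an edgeR adjusted p of 0.309, the log2 fold change was -0.88 ± 0.20 for the aminopeptidase gene RNPEP, -0.75 ± 0.18 for PDCD6IP, which encodes a protein of endosomal sorting, and -0.71 ± 0.18 for RPA1. It was -2.77 for BSCL2, which encodes the lipid droplet protein seipin, -0.83 for COG8, -1.58 for MEIG1, -0.76 for AC010970.2 and -1.42 for RPS2P7, a processed pseudogene. Some rest on low counts, with means in positive and negative cells of 0.63 and 1.91 CPM for MEIG1 and 2.66 and 7.27 for RPS2P7. BSCL2 was at 2.51 and 17.6 CPM, and at 0 in positive 1. RPA1 lies on chromosome 17 at 1829702 to 1900082. The lowest p, 3.88e-05, belonged to PRR3_row3, 1 of 3 rows with the symbol PRR3, at a log2 fold change of -2.44, whereas PRR3_row1 was at 0.32 and PRR3_row2 at -0.04. CBWD5, at -2.09, has near-identical paralogs, and CBWD1, CBWD2 and CBWD7 were at -0.01, 0.05 and 0.38. The estimates for PRR3_row3, CBWD5 and both pseudogenes are uncertain, since reads of such copies can be divided between rows. DESeq2's Wald test called 5 of these 10 genes, PRR3_row3 and CBWD5 at an adjusted p of 0.000226, AC010970.2 at 0.0225, RNPEP at 0.0356 and RPS2P7 at 0.0495, and not RPA1, PDCD6IP, BSCL2, COG8 or MEIG1.

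The senescence markers and secreted factors chosen as single genes before the data were examined had 95% intervals that spanned 0. The log2 fold change was 0.30 (95% interval -0.23 to 0.82) for CDKN1A, which encodes the cell cycle inhibitor p21, 0.50 (-0.65 to 1.65) for MDM2 and 0.16 (-0.21 to 0.53) for GDF15. LMNB1, which encodes a lamin that is lost in senescence, was at -0.66 (-1.53 to 0.21), HMGB2 at -0.01 (-0.54 to 0.52) and the proliferation marker MKI67 at 0.21 (-0.28 to 0.69). GLB1, which encodes lysosomal β-galactosidase, was at 43.5 ± 10.3 CPM in positive and 51.2 ± 4.83 in negative cells (SD, n = 4 each), a log2 fold change of -0.23 (-0.67 to 0.20). Among secreted factors CXCL8 was at 0.54 (-0.05 to 1.13), TGFB1 at -0.02 (-0.34 to 0.30), TGFB2 at -0.26 (-0.61 to 0.09) and CTGF, also called CCN2, at -0.09 (-0.51 to 0.33). The edgeR adjusted p ranged up from 0.373 for CXCL8. Several of these estimates moved when 1 library was left out. Without negative 2 the log2 fold change was -0.12 for LMNB1, 0.14 for MDM2 and 0.10 for CDKN1A. Without positive 1 it was 0.17 for CXCL8, -0.08 for GLB1, 0.10 for GDF15 and 0.03 for MKI67. MDM2 was at 0.85 without negative 8, GDF15 at 0.29 without positive 4, and MKI67 at 0.36 without positive 3, 0.11 without negative 7 and 0.38 without negative 8. HMGB2, TGFB1 and CTGF changed sign with 1 library or another left out and stayed between -0.28 and 0.15. IL6 had between 0 and 17 counts per library and was not tested, and CDKN2A and CDKN2B were not analysed here. In the fixed lists of senescence markers, secretory cytokines and secretory proteases, some members of smallest p had intervals that did not span 0. These were PLAUR (0.09 to 1.43) and CXCL2 (0.12 to 1.88), higher, and BMI1 (-1.20 to -0.06) and CXCL16 (-1.54 to -0.24), lower. None of them passed the threshold in edgeR's test. At an unadjusted p under 0.05 there were 1 higher and 1 lower of 24 senescence markers and 1 and 1 of 18 secretory cytokines. Of 27 secretory proteases and growth factors there were 1 and 0, PLAUR standing in this list too. The share over all tested genes was 14.4%, so these lists do not stand out by this count.

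**Figure D1:**
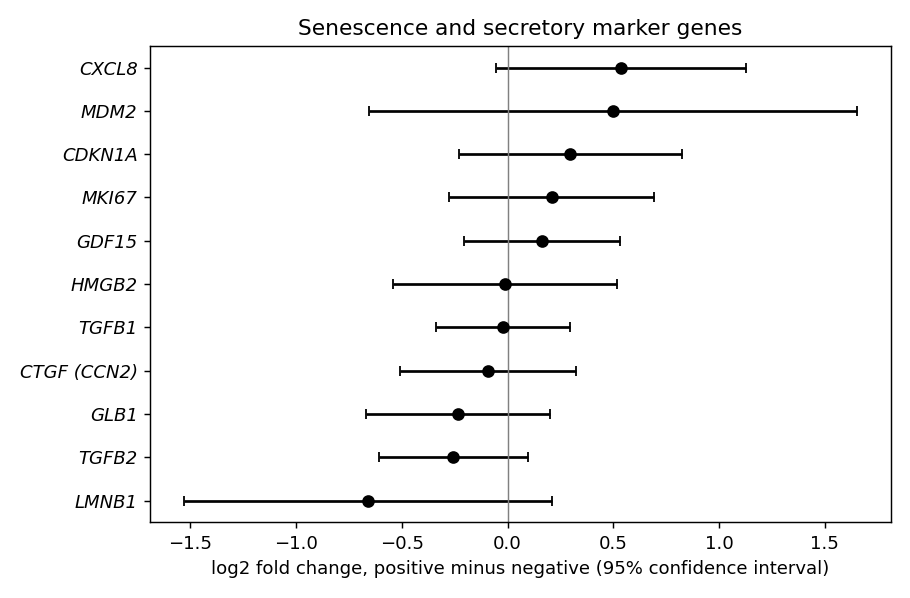
Log2 fold change (positive minus negative, horizontal axis) of 11 tested marker genes in 4 positive and 4 negative libraries. Points are edgeR estimates and bars their 95% confidence intervals, each of which spans 0, from -0.66 for LMNB1 (-0.12 without negative 2) to 0.54 for CXCL8 (0.17 without positive 1).

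The nuclear-encoded genes of oxidative phosphorylation were lower in the positive cells as a group (camera adjusted p = 2.15e-06). With an estimated correlation the call was lost (adjusted p = 0.935 with an estimated correlation). Of 71 tested members 60 had a log2 fold change below 0, and the median was -0.33. The mean log2-CPM of the list was 7.12 ± 0.07 in positive and 7.39 ± 0.19 in negative cells (SD, n = 4 each), with no overlap between groups (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries allow; 0.267 after Benjamini-Hochberg adjustment over 28 lists). Under that adjustment no list could pass unless many lists reached the smallest p. The score difference of -0.27 was -0.17 without negative 2, -0.15 when libraries were scaled by their totals alone and -0.13 without both positive 1 and negative 2, and the exact permutation p was 0.0571 without any 1 of the positive libraries. ATP5O, an ATP synthase subunit, was at -0.83 ± 0.24 (SE), the complex I subunit NDUFA12 at -0.79 ± 0.24 and the complex II subunit SDHC at -0.62 ± 0.19, all with values in every positive library below those in every negative library. ATP5O and NDUFA12 were at -0.54 and -0.48 without negative 2. ATP5O lies on chromosome 21 at 33903453 to 33915980. Negative 2 had the highest score, 7.65, and positive 1 the lowest, 7.02, and without both of these libraries the camera adjusted p was 0.00105. The 7 tested mitochondrially encoded genes, among them MT-CO1, MT-CO3 and MT-ATP6 at log2 fold changes of 1.56, 1.11 and 1.28, had a median of 1.22 and were not called (adjusted p = 0.0816). Without positive 1 these genes were at 0.14, 0.54 and 0.51 and the list's adjusted p was 0.952. The list was called higher without positive 4 (adjusted p = 0.0362), without positive 5 (0.0122), without the low-count filter (0.0109), with DESeq2 (0.00284) and after removal of a length and GC curve (0.0296). Over all 8 libraries its adjusted p = 0.935 with an estimated correlation. All mitochondrially encoded rows together, without TMM scaling, came to 109 CPM in positive 1 and between 9.39 and 23.3 CPM in the other libraries. MT-CO1 alone was at 22.5 CPM in positive 1 and between 1.84 and 3.73 in the others, so these fold changes rest on low counts.

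The NRF2 targets were lower in the positive cells as a group (camera adjusted p = 0.0158), which was lost with an estimated correlation (adjusted p = 0.935 with an estimated correlation). In 24 of 33 tested members the log2 fold change was below 0, with a median of -0.28. The list score was 8.04 ± 0.13 in positive and 8.24 ± 0.05 in negative cells (SD, n = 4 each) without overlap (exact two-sided permutation p = 0.0286, again the smallest possible; 0.267 adjusted over 28 lists). This result depended on the processing. The score difference of -0.19 was -0.07 with scaling by library totals (exact permutation p = 0.343), -0.13 with upper quartile scaling (exact p = 0.2), -0.12 with at least 50 counts (exact p = 0.2) and -0.13 without both positive 1 and negative 2 (exact p = 0.2). The 6 libraries left without these are too few for an exact p under 0.05, so the last p decides nothing. The exact permutation p was 0.114 without negative 2, negative 7 or negative 8, 0.0857 without negative 6, and 0.0571 without positive 4 or after removal of a length and GC curve. UGDH was at -0.40 ± 0.15 (SE), OSGIN1 at -0.74 ± 0.27 and CBR3 at -1.11 ± 0.42. Positive 1 had the lowest score, 7.90. Without both positive 1 and negative 2 the camera adjusted p was 0.0493. Whether other groupings of the libraries also call this list was not tested.

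The NF-kappaB targets were higher in the positive cells as a group (camera adjusted p = 0.0215), a call lost with an estimated correlation (adjusted p = 0.935 with an estimated correlation). The log2 fold change was above 0 in 22 of 28 tested members, with a median of 0.30. NFKBIZ was at 1.1999 ± 0.38 (SE), SOD2 at 0.67 ± 0.22 and TRAF1 at 1.195 ± 0.43, with NFKBIZ at 0.66 without positive 1 and TRAF1 at 1.80 without negative 8. The score was 5.06 ± 0.33 in positive and 4.77 ± 0.08 in negative cells (SD, n = 4 each), without overlap (exact two-sided permutation p = 0.0286, the smallest possible; 0.267 adjusted over 28 lists). The groups were parted narrowly, by positive 5 at 4.861 and negative 8 at 4.859. The exact permutation p was 0.0571 with thinned libraries, without the low-count filter or with at least 50 counts, and 0.0857 with scaling by library totals. It was 0.371 without negative 6, 0.2 without negative 7, 0.114 without negative 2, and 0.0857 without positive 3 or negative 8. The score difference of 0.29 was 0.09 without positive 1 (exact permutation p = 0.229) and 0.16 without both positive 1 and negative 2. Positive 1 stood at 5.55, with the other positive libraries between 4.86 and 4.92, and without positive 1 the camera adjusted p was 0.430. It was 0.214 without negative 6, 0.0511 without negative 7 and 0.0524 without positive 3, and 0.236 without both positive 1 and negative 2.

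Genes of DNA replication and G1/S (camera adjusted p = 0.0158), mitosis and G2/M (0.0173) and the replication-dependent histones (0.00390) were lower in the positive cells as groups, and each call was lost with an estimated correlation (adjusted p = 0.935 with an estimated correlation for each). Below 0 were 38 of 44, 48 of 65 and 19 of 21 tested members, with median log2 fold changes of -0.36, -0.45 and -0.59. Of replication genes TYMS was at -0.59, GINS3 at -0.73, GINS1 at -1.12 and the helicase subunit MCM4 at -0.96. Of mitotic genes the kinase PLK1 was at -1.08, the cyclin CCNA2 at -1.12, BUB3 at -0.70 and RACGAP1 at -0.87, and of the histones HIST2H2BE was at -0.996, HIST1H4H at -0.88 and HIST1H2BF at -0.66. Without negative 2 the log2 fold change was -0.46 for GINS3, -0.30 for GINS1 and -0.26 for MCM4, -0.48 for PLK1, -0.41 for CCNA2 and -0.37 for both BUB3 and RACGAP1, and -0.40, -0.33 and -0.30 for HIST2H2BE, HIST1H4H and HIST1H2BF. Negative 2 had replication, mitosis and histone scores of 5.94, 5.50 and 7.91, above every other library, while positive 1 had the second highest replication score, 5.13. Without negative 2 the camera adjusted p was 0.922 for replication, with the direction turned, 0.700 for mitosis and 0.394 for histones. It was 0.236 and 0.0669 for replication, and 0.454 and 0.0560 for mitosis, without positive 3 and without positive 4. With all 8 libraries, group scores overlapped for all 3 lists (exact two-sided permutation p = 0.600, 0.514 and 0.371). Ribosomal protein genes were lower as a group (adjusted p = 0.0173; 0.935 with an estimated correlation), with 51 of 71 members below 0 and a median of -0.17, and their adjusted p was 0.602 without negative 2 and 0.114 without positive 1. RPL35A was at -1.02 and RPS26 at -0.68, whereas RPL21 was at 1.34. RPL35A and RPS26 were at -0.53 and -0.27 without negative 2, and RPL21 at 0.81 without positive 5.

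**Figure D2:**
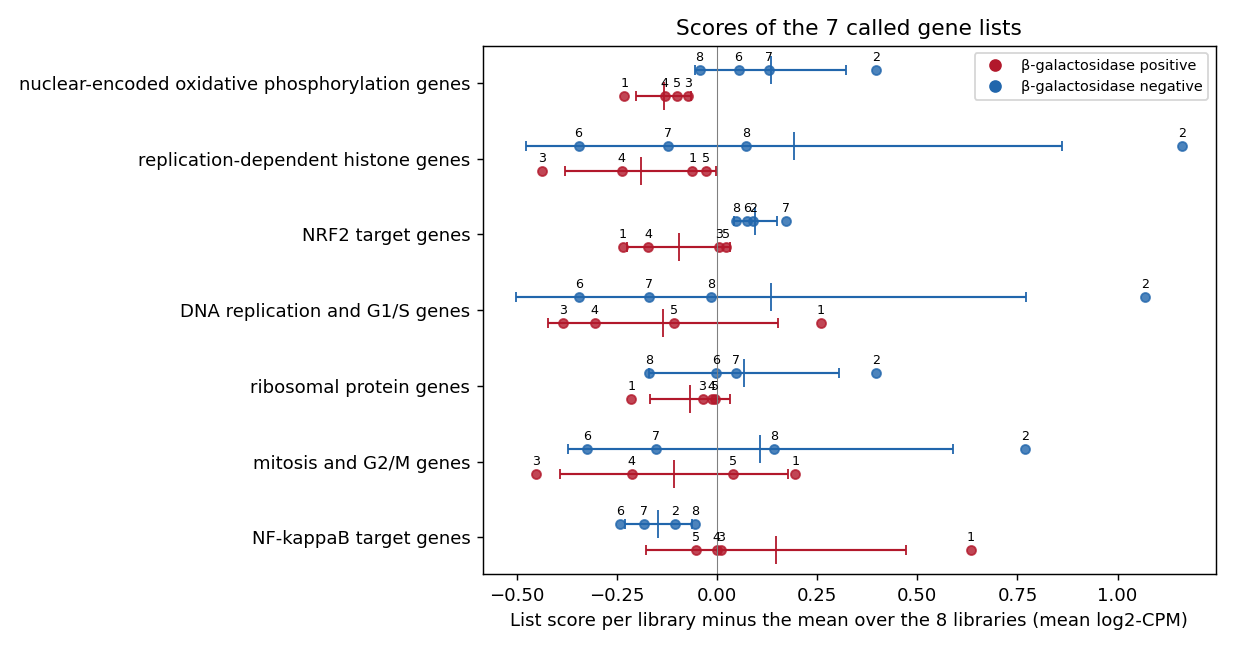
Score of each called gene list (mean log2-CPM of its tested members minus the mean over the 8 libraries, horizontal axis) for 4 positive and 4 negative libraries, with the library number above each point. Vertical ticks and bars are group means and SD. The groups are apart for oxidative phosphorylation, NRF2 and, narrowly, NF-kappaB, and negative 2 is the highest library for replication, mitosis and histones. Over all tested lists the real grouping parted 3, and other groupings of 4 against 4 libraries parted up to 5.

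The other lists that the study's subject leads to were not called by camera. The p53 targets had a median log2 fold change of 0.05 over 48 tested members (camera adjusted p = 0.659), with PIDD1 at 1.43, ASCC3 at -0.52, BLOC1S2 at 0.75 and PLK3 at 0.72. PIDD1 was at 67.6 CPM in positive 1 and between 17.8 and 20.9 in the other positive libraries, and without positive 1 the log2 fold change was 0.74 for PIDD1 and 0.26 for PLK3. Cyclin-dependent kinase inhibitors and senescence markers had a median of -0.15 over 24 members (0.447), with the urokinase receptor gene PLAUR at 0.76, BMI1 at -0.63, H2AFY at -0.43 and CBX5 at -0.37. PLAUR was at 0.42 without positive 1, and H2AFY and CBX5 were at -0.24 and -0.14 without negative 2. Cytokines and chemokines of the senescence-associated secretory phenotype had a median of 0.13 over 18 members (0.923), with CXCL2 at 1.003, CXCL1 at 0.74, CXCL16 at -0.89 and IL32 at -1.04. CXCL2 was at 0.33 without positive 1 and IL32 at -0.28 without negative 2. Its proteases and growth factors had a median of 0.23 over 27 members (0.250), with STC1 at 0.55, PLAT at 0.37 and BMP4 at 0.33. STC1 was at 0.33 without negative 2 and PLAT at 0.58 without negative 8. Fibroblast-activating ligands and TGF-beta pathway genes had a median of 0.02 over 35 members (0.898), with LTBP3 at 0.55, ITGB8 at 0.70, SMAD2 at -0.44 and SMAD7 at 0.48. Lysosome genes had a median of 0.06 over 57 members (0.804), with CTSK at 1.31, TCIRG1 at 0.65, TFE3 at 0.65 and ATP6V0E1 at -0.44, and CTSK was at 0.83 without positive 1.

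Further lists gave no call with all 8 libraries and the methods first chosen. Camera adjusted p and median log2 fold change were 0.923 and -0.05 for autophagy genes, with ATG2A at 0.57, TMEM41B at 0.55 and ATG5 at -0.42, and 0.661 and -0.08 for interferon-stimulated genes, with HERC6 at -0.60 and B2M at -0.43. YAP and TAZ targets were at 0.898 and -0.05, with ARHGEF17 at 0.66, MYOF at -0.61 and VGLL4 at 0.42. Mechanosensor, focal adhesion and actin genes were at 0.363 and -0.14, with ACTN4 at -0.53, PKD1 at 0.80 and TLN2 at 0.56. Epithelial genes were at 0.925 and 0.06, with TJP1 at -0.53 and SPINT1 at 0.76, and mesenchymal genes at 0.923 and 0.01, with COL6A1 at 0.71, COL6A2 at 0.50 and ACTA2 at -0.59. Alveolar and airway genes were at 0.447 and 0.02, with AGER at 1.37, GATA6 at 1.002 and CAV2 at -0.53. Genes of the unfolded protein response and ATF4 were at 0.343 and -0.10, with ATF3 at 1.69, GARS at -0.84 and SARS at -0.56, and hypoxia and glycolysis genes at 0.294 and 0.27, with ENO2 at 1.22, LDHA at -0.68 and PFKFB3 at -0.53. Cholesterol synthesis genes were at 0.363 and -0.10, with FDFT1 at -0.42 and ACAT2 at -0.60. DNA damage repair genes were at 0.567 and -0.09, with BRIP1 at 1.44, MSH6 at -1.002 and RAD51C at -0.56. Immediate early and heat shock genes were at 0.923 and 0.05, with NR4A1 at 0.70 and HSPE1 at -1.08, and BCL2 family and cell death genes at 0.590 and -0.09, with CFLAR at 0.47 and GSDMD at 0.51. ATF3, at 73.2 CPM in positive 1 and between 8.66 and 14.9 in the other positive libraries, and ENO2, at 231 CPM in positive 1 and between 44.6 and 62.3 in the others, were high in 1 positive library. Without positive 1 they were at 0.57 and 0.34, VGLL4 at 0.20, GATA6 at 0.64 and GSDMD at 0.21. Without negative 2 the log2 fold change was -0.26 for ATG5, -0.25 for B2M, -0.32 for LDHA, -0.23 for ACAT2, -0.41 for MSH6 and -0.48 for HSPE1. The unfolded protein response list was called lower without negative 2 (adjusted p = 0.0117) and with 1 surrogate variable (0.0106). Over all 8 libraries its adjusted p = 0.935 with an estimated correlation.

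In the lists together, 0 members passed in edgeR's test over all genes tested, and adjusted over the list alone 1 did, AGER in the alveolar list. DESeq2's Wald test called 1 member over all genes, also AGER (adjusted p = 0.0495). Camera called 7 of 28 lists, 0 with an estimated correlation and fry called 0 (smallest adjusted p = 0.259). The sign of the list median differed from that of the camera test for autophagy, epithelial, mesenchymal and immediate early genes, and the mean differed in sign from the test for epithelial, mesenchymal and immediate early genes.

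Markers of cells that a culture or sort could also hold were compared as summed CPM of library totals, without TMM scaling. Fibroblast markers came to 95.01 CPM in positive and 108 in negative cells (exact two-sided permutation p = 0.457), with ACTA2 the most abundant, and as a list they were not called (camera adjusted p = 0.923; median log2 fold change 0.04). THY1 was at -0.43 and MFAP5 at 0.61, against -0.27 for THY1 without negative 2, and 0.24 without positive 1 and 0.98 without negative 7 for MFAP5. Leukocyte and blood markers came to 248 and 259 CPM (exact two-sided permutation p = 0.8286), of which HBA2 made up the most, with HBA2 at -0.28, HBB at -0.23 and LYZ at 0.17. Over the libraries left out in turn HBA2 ranged from -0.73 without positive 1 to 0.02 without negative 6, HBB from -0.66 without positive 1 to -0.09 without negative 6 and LYZ from 0.08 without negative 6 to 0.28 without negative 8. Endothelial markers came to 59.3 and 42.4 CPM (exact two-sided permutation p = 0.114), with EGFL7 at 0.41 and TIE1 at 0.37, the latter 0.21 without negative 2, 0.19 without negative 6 and 0.72 without negative 8. The leukocyte and endothelial lists had 4 and 2 tested members and were not tested as lists.

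Positive 1 and negative 2 stood apart from the other 6 libraries. Component 1 of the log2-CPM values held 41.6% of the variance and component 2 held 21.4%. On component 1 positive 1 (-41.3) and negative 2 (72.5) were the ends. Each positive library lay below each negative one, the nearest being positive 3 at -10.2 and negative 8 at -3.68. This order was not tested. The root mean square log2 distance of a library from the mean of the others was 0.696 for positive 1 and 0.826 for negative 2, against 0.359 to 0.467 for the rest. Positive 1 also had the fewest counts and negative 2 the most. Of 120 genes named here, the log2 fold change moved by more than 1.5 times without negative 2 for 33 and without positive 1 for 23, against 3 to 9 without any other library.

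**Figure D3:**
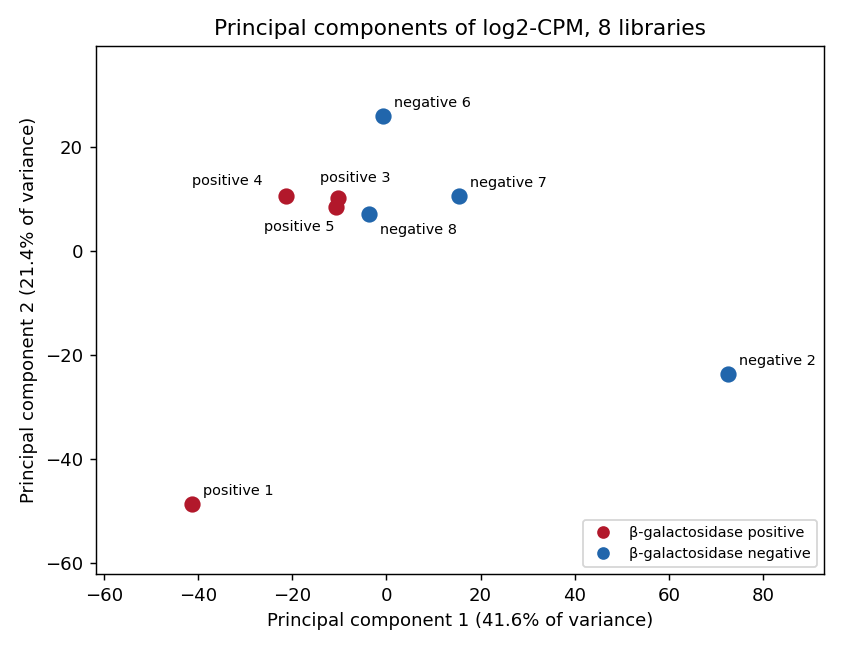
Principal components 1 (41.6% of variance, horizontal axis) and 2 (21.4%, vertical axis) of the log2-CPM values of the 8 libraries, 1 point per library. Positive 1 and negative 2 lie apart from the other 6 libraries, and each positive library lies below each negative one on component 1.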

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

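The tests of thinning and of length and GC content on the distances of positive 1 and negative 2 were written down before their results were seen. The tests that used other splits of the libraries, swapped labels, the 6 remaining libraries, nuclear-retained transcripts, and length and GC content on the oxidative phosphorylation genes were chosen only after the result each bears on had been seen.

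Positive 1 and negative 2 lay far from the other 6 libraries. Depth is argued against by thinning every library to the smallest total, which left the nearer of them at a distance of 0.685, above the largest of the other 6, 0.458. The amplicons were not modelled. For annotated transcripts, length and GC content are argued against by the removal of both curves, which left the nearer of these libraries at 0.677 against 0.448. A swap of their labels cannot be told apart from correct labels, because the correlation across genes, which are not independent replicates, between positive 1 minus negative 2 and the contrast of the other 6 libraries was 0.382 for the real split and up to 0.339 for the others, and 20 splits are too few for a share under 0.05. What set the libraries apart stays open, and no biological explanation was tested because the labels give neither culture nor batch.

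The oxidative phosphorylation genes were lower in the positive cells by a score difference of -0.27, which was -0.17 without negative 2, -0.15 with scaling by library totals and -0.13 without both far libraries. A trend over the length and GC content of annotated transcripts is argued against as the whole cause, since the difference was -0.19 after its removal, beyond the pooled SD of 0.0959. The length and GC content of the amplicons were not modelled, so a trend over these stays untested. Chance in the grouping was not excluded, as 2 of the 35 splits of the 8 libraries, the real one included, gave an adjusted p as small, and the smallest of the other splits was 7.77e-07. Most other splits that part positive 1 and negative 2 also gave a camera adjusted p under 0.05 for this list, such as 1.06e-05 and 2.35e-06. A higher share of nuclear-retained RNA in the positive cells is a candidate explanation that cannot be told apart from a difference in the genes themselves. The mean score of such transcripts was 0.51 higher in the positive cells, or 0.32 without positive 1, with overlapping groups (exact two-sided permutation p = 0.2 with all 8 libraries). Their unadjusted camera p was 0.000320 with the preset and 0.196 with an estimated correlation, against 0.104 for oxidative phosphorylation with an estimated correlation. A difference that goes with the staining stays open as well.

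There were 1631 genes with an unadjusted p under 0.05. Over all 35 splits of the libraries chance in the grouping is argued against, since 1 split, the real one, gave as many and the highest of the others gave 1264, but the 15 splits with positive 1 and negative 2 on one side gave 160 to 770. Among the 20 splits that part these libraries, as the real one does, 1 gave as many, the real one, and 20 splits are too few for a share under 0.05. Whether positive 1 and negative 2 alone may give the excess cannot be told apart from a difference between the groups, because the 6 remaining libraries gave 1145 genes against a highest other count of 917, and their 10 splits are too few for a share under 0.05. A surrogate variable reduced the count to 529. It was highest in negative 2 and higher in each negative than in each positive library, narrowly so at -0.0969 in negative 6 and -0.104 in positive 3. Fitting it also takes out part of the group contrast, so the lower count decides nothing. A difference that goes with the staining remains a hypothesis.

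For the count of genes past an adjusted p of 0.05 in edgeR's test, which was 0 (1631 at an unadjusted p under 0.05, and 45 past the threshold in DESeq2's Wald test and 0 in limma voom), the splits decide nothing, since all 35 of 35 give at least 0; the highest other count was 1. For the lists called by camera with the preset correlation, 23 of the 35 splits gave at least the real count of 7, and the highest other count was 13, so chance was not excluded. The scores of 3 lists were without overlap in the real split, against 3 in another split and 5 in a further one. That count alone therefore does not set the real grouping apart.

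Single libraries far from the rest of their group of 4 were sought by the gap to the nearest library as a share of the group's range. Of 304 groups of values checked, 49 stood out, 22 of them through negative 2 and 19 through positive 1, where chance gives about 1 in 20 or 15.2. The share was 0.901 for the total count of positive 1, 0.936 for its mitochondrial CPM, 0.960 for the mitochondrial CPM of negative 2, 9.39 against 19.2 to 19.6, and 0.912 for the noncoding share of negative 6, 0.747%. Of list scores it was 0.908 for NF-kappaB targets, 0.873 for hypoxia and glycolysis genes and 0.854 for ribosomal protein genes in positive 1, and 0.898 for secretory proteases and growth factors and 0.846 for cholesterol synthesis genes in negative 2.

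Among the named genes the same share was taken of CPM values. In negative 2, which was far from the other negative libraries in each case, this share was 0.872 for MYL5, 0.902 for RPA1, 0.870 for GINS1, 0.922 for MCM4, 0.908 for PLK1, 0.871 for CCNA2 and 0.953 for BUB3. For negative 2 it was also 0.886 for RACGAP1, 0.834 for HIST2H2BE, 0.943 for HIST1H4H, 0.940 for IL32, 0.860 for STC1, 0.843 for ATP6V0E1 and 0.865 for B2M. It was moreover 0.900 for MYOF, 0.881 for EGFL7, 0.914 for ACAT2, 0.891 for MSH6 and 0.870 for HSPE1. In positive 1, set against the other positive libraries, it was 0.937 for PIDD1, 0.962 for CXCL2, 0.900 for CTSK, 0.902 for TRAF1, 0.855 for VGLL4 and 0.927 for PKD1. For positive 1 it was also 0.940 for MFAP5, 0.922 for HBA2, 0.944 for HBB, 0.903 for ATF3, 0.833 for CBR3, 0.905 for ENO2 and 0.908 for MT-CO1. It was moreover 0.845 for MT-ATP6. In other libraries it was 0.938 for CBWD5 in negative 8, 0.876 for PLK1 in positive 5, 0.878 for CCNA2 in positive 5, 0.967 for ATG2A in positive 5, 0.861 for MFAP5 in negative 7, 0.833 for HBB in negative 6 and 0.918 for RAD51C in positive 3.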

How the results depend on the processing

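Leaving out both positive 1 and negative 2, summing rows of 1 symbol and removing the length and GC curve were chosen after seeing the data, and all other alternatives before. The count of genes past an adjusted p of 0.05 was 0 under every edgeR and voom alternative that used all libraries. DESeq2's Wald test gave 45 genes, 37 higher and 8 lower, and the cause was not tested. Leaving out 1 library gave 0 to 1 genes past the threshold, 0 higher and 0 to 1 lower, namely TBRG1 without negative 6 and CBWD5 without negative 8, TBRG1 being named after its value was seen. At an unadjusted p under 0.05 these left 1117 to 1980 genes, with 1117 without negative 2 and 529 with 1 surrogate variable. Of 125 named genes, 11 had a change of sign in some alternative, in 24 of 2473 gene and setting pairs, and none of these was called, while 16 pairs were newly called in the same direction. The 20 genes of smallest p kept their sign throughout. With rows of 1 symbol summed, PRR3 had a log2 fold change of -0.05.

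The lists called numbered 7, but 4 with 1 surrogate variable, 2 without both far libraries, 0 with an estimated correlation and 0 by fry. Leaving out 1 library gave 4 to 8 lists, with 4 without negative 2 and 4 without positive 3. Over these the adjusted p ranged from 0.000115 to 0.922 for DNA replication, whose direction turned without negative 2, from 6.30e-05 to 0.700 for mitosis, from 0.358 to 0.998 for p53 targets, from 0.700 to 0.998 for secretory cytokines, from 0.737 to 0.998 for fibroblast-activating ligands and from 0.279 to 0.998 for lysosome genes. Replication and mitosis were no longer called without negative 2, positive 3 or positive 4. NF-kappaB was not called without the low-count filter (0.0854) or by voom (0.0763), NRF2 with at least 50 counts (0.0676), and ribosomal proteins with at least 50 counts (0.0928), by voom (0.319) or with the length and GC curve removed (0.316). Oxidative phosphorylation was called under 21 of 23 alternatives, all but an estimated correlation and fry. Most other splits that part positive 1 and negative 2 also called it, so these calls do not set the real grouping apart. Lists were not tested with robust estimation off, which does not enter camera. With 1 surrogate variable the adjusted p was 0.0630 for DNA replication, 0.459 for mitosis, 0.570 for histones and 0.592 for ribosomal proteins, all with the direction turned, and 0.560 for p53 targets, 0.570 for secretory proteases, 0.774 for fibroblast-activating ligands and 0.146 for lysosome genes, which were uncalled and changed sign. Without both far libraries it was 0.128 for DNA replication, 0.0586 for mitosis, 0.128 for histones, 0.870 for ribosomal proteins and 0.996 for p53 targets. With an estimated correlation it was 0.935 for DNA replication and for mitosis, and by fry 0.774 for both. With members of 1 list only it was 0.998 for p53 targets and 0.460 for secretory cytokines. The surrogate variable was higher in each negative than in each positive library, so fitting it also takes out part of the group contrast. The cause of the other changes was not tested, beyond the fewer libraries or members that some alternatives hold.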

Other observations

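All tests here were chosen after the libraries had been seen. Transcripts that are often retained in the nucleus had their highest mean score in positive 1, 6.39, followed by negative 8, 5.81, with the other positive libraries between 5.41 and 5.79, so that the groups overlapped (exact two-sided permutation p = 0.2). Of 30 such genes 24 were tested, 0 of them in another fixed list, 18 had a log2 fold change above 0, and the median was 0.45, or 0.30 without positive 1. The cyclin genes CCNL1 and CCNL2 were at 1.43 and 1.33, GOLGA8A at 1.41, AHSA2 at 1.05, and NKTR at 0.93, while SRSF7 was at -0.28 and CLK4 at -0.26. CCNL1, CCNL2 and NKTR were at 0.76, 0.68 and 0.60 without positive 1, and CLK4 at -0.08 without negative 2. In edgeR's test 0 of the 24 passed (adjusted p of 0.309 or more) and 8 had an unadjusted p under 0.05, while DESeq2's Wald test called 1, GOLGA8A (adjusted p = 0.0495). As a list they were higher in the positive cells by camera with the preset correlation (p = 0.000320, and from 7.53e-05 to 0.00832 with 1 library left out, the highest without positive 1, and 0.0324 without both positive 1 and negative 2). With an estimated correlation p = 0.196, and by fry p = 0.0911, both unadjusted. The unadjusted p for oxidative phosphorylation was 0.104 by camera with an estimated correlation and 0.0277 by fry. The score was 5.83 ± 0.41 in positive and 5.33 ± 0.41 in negative cells (SD, n = 4 each), a difference of 0.51, or 0.32 without positive 1. Across the 8 libraries it went with a lower oxidative phosphorylation score (Pearson r = -0.889, exact permutation p = 0.00402; Spearman rho = -0.738, exact permutation p = 0.0458), the 1 relation computed. Without positive 1 and negative 2, the libraries farthest from the median, r was -0.667, and with group means removed it was -0.836. A shared dependence of both scores on RNA handling or on the state of the cells may underlie the relation, and the data do not separate these.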
